A study of Homo sapiens with 82 samples.

How the data were processed

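The series holds poly(A) RNA-seq of 82 breast cell lines, all described by the labels as cancer cell lines, with 1 library per line. The labels give no replicate, control, subtype, batch or lane, so all lines formed 1 group. Lines are named by the columns of the series table. In 2 of the single-line files, those of EFM19 and EFM192A, the header names the other of these lines, and in 2 samples, HBL100 and HCC1008, the cell line tag differs from the title, in which case the title was used. None of these conflicts could be resolved from the files.

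The deposited values are FPKM, made by the authors with STAR 2.3.0 and Cufflinks 2.2.1 on hg19, per the submitters' processing notes. The gene annotation used for counting is not given in the sources used here. The table lists 29127 genes, and the 82 single-line files held the same values as the table, with a largest difference of 0. Of the genes, 3510 were at 0 in every line. The values carry no read counts. Low values were examined for whole-read steps, and in 5025 of 10016 genes (50.2%) the lowest value lay under 0.1 of the median low value. Whole reads in lines of unlike depth can give such values too, so the check does not settle whether steps exist. Depth is unknown and no counting interval is given. In 20 genes that reached 1 FPKM in all other lines there were 169 exact zeros, among them EEF1A1 in 5 lines, GAPDH in 1 line and FTH1 in 1 line. They were used as deposited, with a replacement as an alternative.

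Values were analysed as log2(FPKM + 1) for the 15952 genes with at least 1 FPKM in at least 5 lines. Gene lists, anchor genes, tests and thresholds were set before the data were examined. There were 32 lists. The list of mitochondrially encoded genes could not be tested because none of its 11 genes is in the files. TAP2 and PECAM1 are also absent, and UGT2B28, SOX10 and FGF19 fell under the filter. Coherence of a list was its mean pairwise Spearman rho, tested against 10000 random lists drawn from 20 bins of mean expression. Principal components were computed on centred values, and lists were tested on components 1 to 3 by the median correlation of their members against 10000 random lists.

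Each of 8 anchor genes was regressed on by all other genes with limma 3.58.1 in R 4.3.3. An anchor or list score was split into clusters with mclust 6.1.1 where the BIC difference exceeded 10, Ashman's D exceeded 2 and each cluster had at least 6 lines, and scans were run in clusters of at least 10 lines. List scores were mean z scores of the members, and relations between scores were tested with 100000 permutations, except that the alternatives used normal-theory p-values. All p-values were adjusted by the Benjamini-Hochberg method within their family. Levels of receptors, oncogenes and tumour suppressors were compared with the median in robust SDs, with 3 as the limit and no test. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The p-values of the scans and of the relations measure spread between lines, since no line was measured again. They treat the lines as independent, although some lines are related or very similar, so they may be too small. The alternative without 4 related lines keeps other close pairs, such as SUM149 with SUM229 (r of 0.975) and ZR751 with ZR75B (0.929). The p-values of list coherence and of lists on components compare a list with other genes over the same lines, and carry no spread between lines.

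On simulated data of 15951 genes, the MKI67 scan recovered 5 of 50 genes planted at r of 0.4, 49 of 50 at 0.6 and 50 of 50 at 0.7 and 0.8, with 0 false calls. Only this scan, which uses all lines, was simulated, so recovery within the smaller clusters is unknown. The 0 false calls cannot be carried over either. With anchors permuted on the real data, up to 130 genes were called among the lower CDH1 lines and 38 among the lower ERBB2 lines. The highest count in any other scan was 7, and it was 1 for MKI67. On 15952 genes the coherence test recovered 8 of 8 lists planted at a correlation of 0.3 and called 0 of 21 lists without signal. Recovery of weaker lists was not tested.

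The genes named are the 25 with the largest SD, up to 4 members of each list with the highest mean rho and the 1 with the lowest, the 10 receptors or oncogenes and the 10 tumour suppressors with the largest range, up to 20 genes with the highest and 10 with the lowest r in each scan, and 10 genes at each end of each component, or a part of these. Other list members named in the scans, and CD14, CD68, PTPRC, CD3E, MED1, CDK12, EPCAM, FN1 and MYC where their levels or r are given, were chosen after their values were seen. XIST and genes of the Y chromosome were left out of all named genes.

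The alternatives were a pseudocount of 0.1, no expression filter, a mean of at least 1 FPKM (13881 genes), scaling to the same upper quartile, leaving out 4 lines that catalogues relate to others (AU565, LY2, KPL1 and MB157), Pearson for Spearman correlation in coherence and the reverse in the scans, removal of 2 components, Ashman's D over 3, leaving out the 2 lines farthest from the median, and genes scaled to unit variance. Alternatives added later are named in the closing section. Gene order for neighbouring genes came from the GRCh38.p14 RefSeq table, which differs from hg19, and no coordinates are given.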

Results

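Gene expression was measured in 82 breast cell lines, each represented by 1 poly(A) RNA-seq library. The labels describe every sample as a breast cancer cell line and give no subtype, replicate or control, so the lines form 1 group and each line contributes 1 value. A difference between single lines therefore has no replicate check, and the tests below ask how genes vary together over the lines. The summed FPKM per line ranged from 309407 in DU4475 to 695032 in BT20, with a median of 517665. Between 11394 genes in ZR7530 and 12978 genes in HCC1937 reached 1 FPKM. The share of the summed FPKM taken by the 10 highest genes ran from 4.74% in BT483 to 15.9% in MDAMB415. Read depth is unknown, because the values are FPKM and carry no read counts. For scale, AU565 and SKBR3, which catalogues list as having a shared origin, differed by a median of 0.29 on the log2 scale per gene, against 0.63 for the median pair of lines. EFM19 and EFM192A are named here by the column of the series table. The separately deposited files of these lines carry each other's name, so a value given for either may belong to the other.

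The 25 genes that varied most between the lines included genes of secreted proteins, keratins, S100 proteins, metabolic enzymes and mesenchymal proteins. These classes were named after the genes were seen and were not tested. SCGB2A2, which encodes mammaglobin A, had the highest SD of all genes, 4.14 on the log2(FPKM + 1) scale, with a median of 1.32 FPKM, 38811 FPKM in MDAMB415, 36557 FPKM in ZR7530 and a value listed at 0 in 14 lines. The trefoil peptide gene TFF1 had an SD of 3.89, a median of 2.01 FPKM and a highest value of 6235 FPKM in MDAMB330, and TFF3 had an SD of 3.60 and a highest value of 3787 FPKM in UACC812. Other secretory genes in this set were MGP, with 13824 FPKM in MDAMB330, AGR2, with 2645 FPKM in SUM52, MUCL1, with 6130 FPKM in SUM190, AZGP1, with 4546 FPKM in SUM190, LCN2, with 7061 FPKM in HCC1569, and SAA1, with 1810 FPKM in 184B5.

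Keratins and mesenchymal genes were abundant in some lines and near absent in others. The basal keratin gene KRT5 had quartiles of 0.25 and 58.9 FPKM and reached 4212 FPKM in 184A1, and KRT17 reached 3585 FPKM in the same line. The luminal keratin gene KRT19 had a median of 482 FPKM but only 0.161 FPKM in HCC1395. VIM, which encodes the intermediate filament protein vimentin, had quartiles of 0.407 and 125 FPKM and a highest value of 2983 FPKM in SUM1315, and SPARC, a matrix protein gene, reached 8112 FPKM in HS578T. CAV1 and TGFBI were also highest in HS578T, at 1076 and 1836 FPKM. Metabolic genes were among the most variable as well. GSTP1, which encodes a glutathione transferase, had quartiles of 0.402 and 348 FPKM, and the lactate dehydrogenase subunit gene LDHB had quartiles of 0.823 and 443 FPKM. The S100 genes S100A2, S100A9, S100A14 and S100P, with SDs from 3.29 to 3.47, and IGFBP5, KRT81 and AKR1B1 completed the 25 genes. These SDs have no test. All 25 stayed within 1.5 times their value under each of the 8 alternatives run for them.

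The first question was whether genes that share a function or a chromosomal region rose and fell together over the 82 lines. They did so in 27 of 31 gene lists with at least 3 measured members, by a mean pairwise Spearman rho above that of random lists of equally expressed genes. HLA class I antigen presentation genes had the highest mean rho, 0.71 over 10 genes, and PSMB9, HLA-B and TAP1 followed their list most closely, with mean rho values of 0.76, 0.76 and 0.75. Proliferation genes came next, with 0.69 over 19 genes, led by CCNA2 and AURKB at 0.75 each. The interferon-stimulated genes had a mean rho of 0.63 over 19 genes, led by IFIT1 at 0.74 and IFI44 at 0.71, and IFIT1 ran from a lower quartile of 0.875 FPKM to 309 FPKM in CAL851. The ribosomal protein genes had 0.62 over 14 genes, where random lists already gave a median of 0.11. In that list RPL19 was the member with the lowest mean rho, 0.48, and its highest value was 35436 FPKM in EFM192A against a median of 1049 FPKM.

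Lineage lists were coherent in the same way. Luminal epithelial genes had a mean rho of 0.59 over 12 genes, led by the transcription factor genes FOXA1 at 0.68 and SPDEF at 0.66 and by ERBB3 at 0.67. ELF3 followed them least, at 0.31. Basal and myoepithelial genes had 0.51 over 16 genes, with KRT5, KRT6A and KRT6B at 0.59 each, although reads of the near-identical KRT6 copies cannot be told apart with certainty. The epithelial junction list had a mean rho of 0.44 over 14 genes, led by ESRP2 at 0.51, and the mesenchymal list 0.40 over 17 genes, led by CAV1 at 0.54 and AXL at 0.53. Oestrogen response genes had 0.39 over 13 genes, where STC2 stood apart at 0.08. Androgen and apocrine genes had 0.25 over 9 genes, led by PIP at 0.40 and AR at 0.38, while FKBP5 had a mean rho of −0.07. The luminal progenitor list was the weakest of the called lists, 0.12 over 7 genes, with an adjusted p of 0.0204.

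Genes that lie together on a chromosome formed a further set of coherent lists. The 17q23 region had a mean rho of 0.59 over 13 genes, led by RPS6KB1 at 0.69 and APPBP2 at 0.66, and RPS6KB1 reached 357 FPKM in KPL1 against a median of 19.02 FPKM. The 11q13 region around CCND1 had 0.51 over 7 genes, led by PPFIA1 at 0.62 and FADD at 0.61. The 8p11 region had 0.51 over 15 genes, led by ASH2L at 0.63, while FGFR1, the receptor gene the region is often named for, was not among the 4 leading members. The 17q12 region around ERBB2 had 0.47 over 13 genes, led by STARD3 at 0.59 and GRB7 at 0.57, and MED1 was lowest at 0.30. Lower values were found for the 9p21 region around CDKN2A, 0.37 over 6 genes, the 8q24 region around MYC, 0.27 over 10 genes, and the 20q13 region, 0.13 over 9 genes.

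Among stress and metabolic lists, ATF4 targets had a mean rho of 0.41 over 10 genes, led by CHAC1 at 0.55 and the asparagine synthetase gene ASNS at 0.53. Cholesterol synthesis genes had 0.37 over 13 genes, led by HMGCS1 and FDFT1 at 0.47 each. NRF2 targets had 0.28 over 12 genes, hypoxia genes 0.21 over 13 genes and p53 targets 0.21 over 16 genes, the last led by CDKN1A at 0.35. Housekeeping genes had 0.22 over 13 genes, with an adjusted p of 0.00155. HLA class II genes had 0.57 over 8 genes, led by CD74 at 0.63, although most lines expressed little of them, and CD74 had a median of 0.637 FPKM and 549 FPKM in MDAMB231. Cancer-testis antigen genes had 0.40 over 12 genes, led by MAGEA3 at 0.55, and reads of the near-identical MAGEA copies may be split between them. Of the leukocyte markers, 4 of 12 passed the expression filter, with a mean rho of 0.33, among them CD14 with a highest value of 177 FPKM in MDAMB415 and CD68 with 147 FPKM in MDAMB157. PTPRC, which encodes CD45, and CD3E did not pass the filter.

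The 4 lists that were not called held 3 endothelial markers (mean rho 0.0025), 3 melanocyte markers (0.019), 30 receptors and oncogenes (0.015) and 22 tumour suppressors (0.041), with adjusted p-values of 0.62, 0.53, 0.69 and 0.53. All p-values here are one-sided, from 10000 random lists matched on mean expression, with Benjamini-Hochberg adjustment over the 31 lists. For most called lists p was 1e-04, the smallest these lists can give, with an adjusted p of 0.000141. Without the expression filter the leukocyte list lost its call, with a mean rho of 0.037 over 12 genes and an adjusted p of 0.171.

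**Figure D1:**
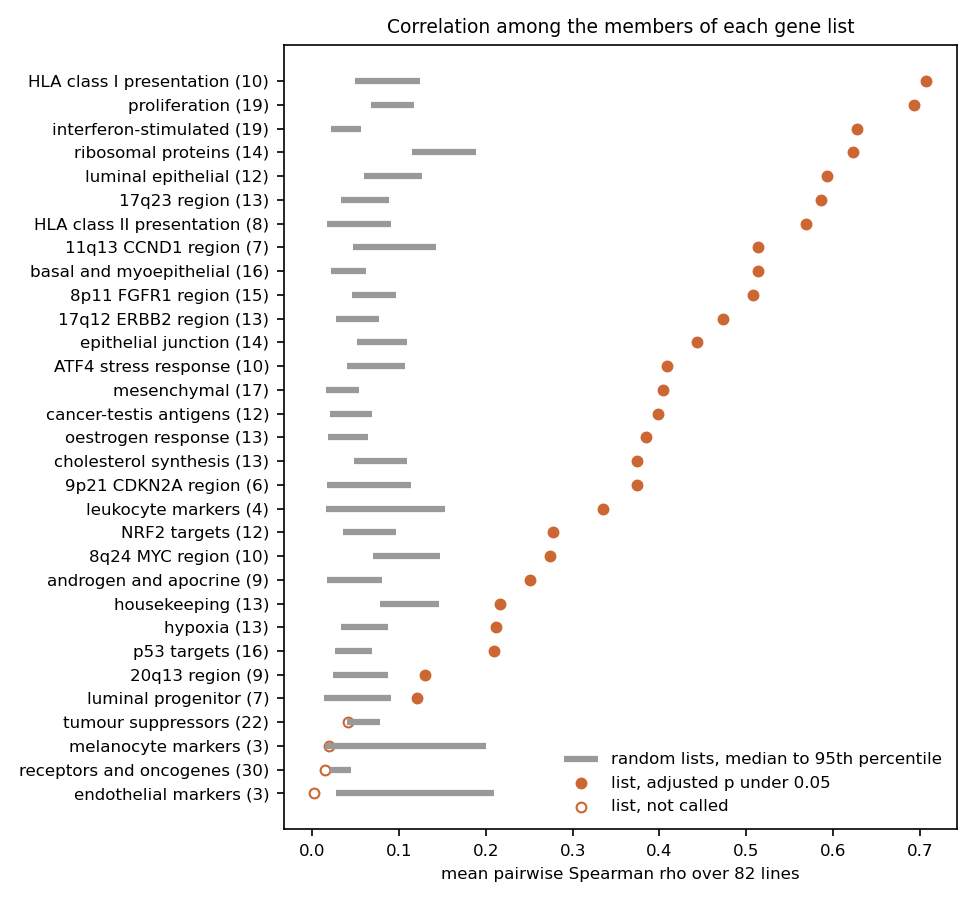
Mean pairwise Spearman rho over 82 lines (x axis) for each of 31 gene lists (y axis, number of genes tested in parentheses), with points for the lists and grey bars for the median to the 95th percentile of 10000 random lists matched on expression. The 27 called lists run from 0.12 for the luminal progenitor list to 0.71 for HLA class I presentation, and the 4 open points lie within their random lists.

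The second question was which axes of difference separate the lines. The main axis ran from luminal to mesenchymal lines and held 15.9% of the variance, or 9.97% with genes scaled to unit variance. At its negative end stood the luminal transcription factor genes SPDEF and FOXA1, each with a correlation of −0.93 with the component, and at its positive end KIRREL at 0.93, the caveolae genes CAV1 at 0.91, PTRF at 0.90 and CAV2 at 0.88, and the transcription factor genes ETS1 at 0.91 and FOSL1 at 0.88. HCC1419, HCC712 and BT483 were the lines farthest to the luminal side, and HS578T, SUM159 and SUM1315 the farthest to the other. All 12 luminal epithelial genes and all 14 epithelial junction genes had negative correlations, with medians of −0.73 and −0.60. All 17 mesenchymal genes, all 16 basal genes and all 10 HLA class I genes had positive ones, with medians of 0.61, 0.48 and 0.51. Androgen and apocrine genes (median −0.58), oestrogen response genes (−0.50), the 17q12, 11q13 and 17q23 regions (−0.38, −0.35 and −0.29) and interferon-stimulated genes (0.30) were the other called lists.

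Components 2 and 3 held 6.79% and 4.83% of the variance. Component 2 set proliferation genes, all 19 negative with a median of −0.62, against basal genes, all 16 positive with a median of 0.49, and 13 of 14 epithelial junction genes, with a median of 0.39. The other called lists on it were the 8p11 region (median −0.32), ATF4 targets (0.20), p53 targets (0.18), ribosomal proteins (0.17), NRF2 targets (0.13), the 8q24 and 17q12 regions (0.10 each) and interferon-stimulated genes (0.07). TUBA1A and TUBA1B, which encode alpha tubulins, had −0.85 and −0.79, the mitotic genes CENPO, PBK and HJURP −0.75, −0.75 and −0.74, and ALS2CL and PERP, an adhesion gene, 0.74 and 0.73. The lines at the positive end were 184B5, MCF12A, SUM102, 184A1 and MCF10A, of which 184B5, MCF12A, 184A1 and MCF10A are catalogued as derived from non-tumour breast tissue, and those at the negative end BT549, MDAMB157 and CAL51. Component 3 had proliferation genes (median 0.45), HLA class I genes (0.37), interferon-stimulated genes (0.36), epithelial junction genes (0.34), housekeeping genes (0.33), luminal progenitor genes (0.31), HLA class II genes (0.25) and cancer-testis antigens (0.22) on its positive side. CARHSP1 had the highest r, 0.67. On the other side were p53 targets (−0.24), ribosomal protein genes (−0.17), mesenchymal genes (−0.16) and the 17q23 and 8p11 regions (−0.09 and −0.06), with MBLAC2 at −0.60 and XPC, a DNA repair gene, at −0.57. HCC1954, MDAMB468 and HCC1937 were highest on it, and DU4475 was lowest.

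On components 1, 2 and 3, 11, 11 and 13 lists were called by a two-sided test against 10000 random lists, with Benjamini-Hochberg adjustment over lists and components. Calls are relative to the random median, which was −0.095 for interferon-stimulated genes on component 2 and 0.118 for the 8p11 region on component 3. Oestrogen response genes, at −0.24 on component 2 against a random −0.09, were not called. Random genes were drawn singly, so a list whose members move together may be called more easily. The number on component 2 was 18 at a pseudocount of 0.1, and that on component 3 was 7 with genes scaled to unit variance and 6 without 184A1, 184B5, MCF10A and MCF12A. Library measures moved with the components too, in a family of 24 relations. Component 2 correlated with the upper quartile of FPKM over 82 lines, with Pearson's r of −0.52 (permutation p = 1e-05, adjusted p = 8e-05), Spearman's rho of −0.49 (permutation p = 1e-05) and r of −0.54 without the 2 lines farthest from the median. Component 3, on which housekeeping genes were called, correlated with the same measure, with r of 0.55 (permutation p = 1e-05, adjusted p = 8e-05), rho of 0.49 (permutation p = 2e-05) and r of 0.50 without the 2 farthest lines. The housekeeping score itself had r of 0.80 with the upper quartile. For component 1 the largest of these was the share of histone gene FPKM, with r of −0.38 (permutation p = 0.0005, adjusted p = 0.0024), rho of −0.40 (permutation p = 0.00021) and r of −0.42 without the 2 farthest lines.

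**Figure D2:**
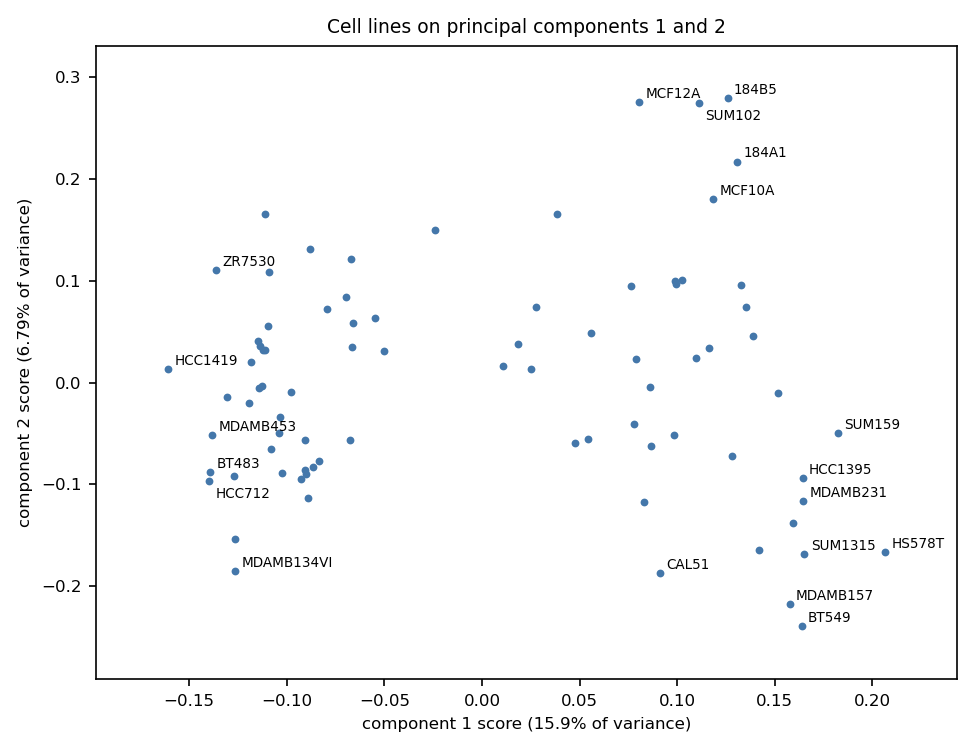
Scores of the 82 lines (1 point each, no unit) on component 1 (x axis, 15.9% of the variance) and component 2 (y axis, 6.79%), with the lines at the ends named. HS578T lies farthest to the positive side of component 1 at 0.207 and HCC1419 farthest to the negative side at −0.161, and 184B5, MCF12A and SUM102 lie highest on component 2, from 0.275 to 0.279.

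The third question was which genes followed 8 anchor genes of breast cancer biology: ESR1, ERBB2, AR, EGFR, CDH1, VIM, MKI67 and CDKN2A. Their Ensembl identifiers in the files are ENSG00000091831, ENSG00000141736, ENSG00000169083, ENSG00000146648, ENSG00000039068, ENSG00000026025, ENSG00000148773 and ENSG00000147889. A mixture model split AR, CDH1, CDKN2A, EGFR, ERBB2 and VIM into separate lower and upper clusters of lines, within which the correlations were computed. These clusters were drawn from the values and are not groups of the study. A gene was called at an absolute Pearson r of at least 0.5 and a limma Benjamini-Hochberg adjusted p under 0.05. List members were also adjusted over their list alone, with the same limit on r. Over many lines that limit already implies a small p, so the second adjustment could hardly change a count. Equal counts there are no added support. With the anchor's values permuted over the lines 100 times, no permutation called as many genes as the real order in the scans of ESR1, MKI67, the lower ERBB2 and VIM lines and the upper AR, EGFR, CDH1, VIM and CDKN2A lines. The highest permuted count in these was 38, among the lower ERBB2 lines.

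**Figure D3:**
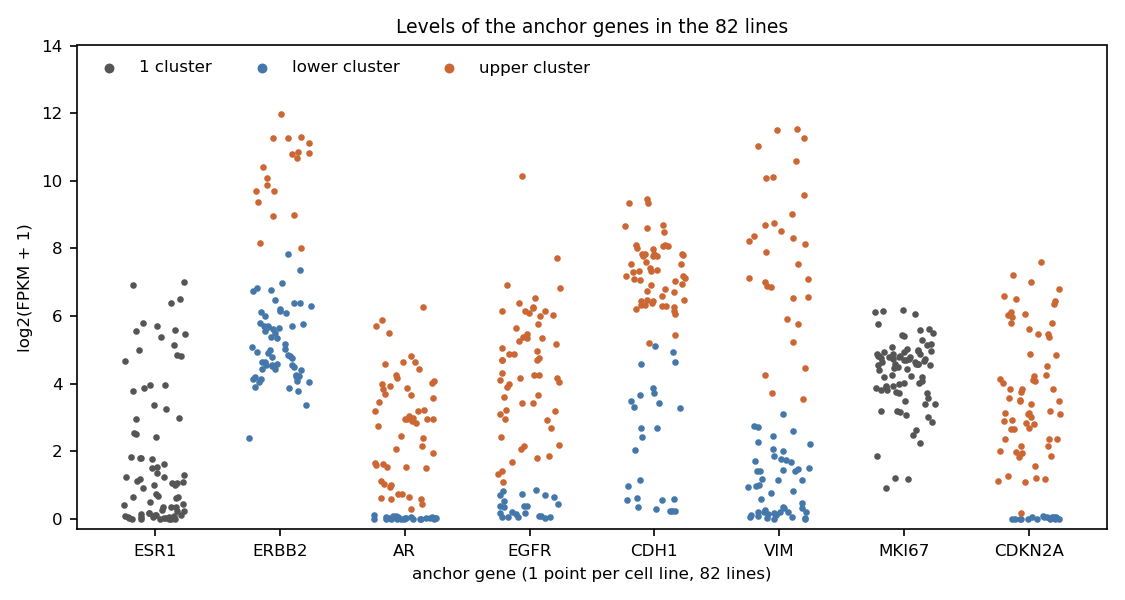
Level of each anchor gene (x axis) as log2(FPKM + 1) (y axis), 1 point per line, with the lower cluster in blue, the upper cluster in orange and genes in 1 cluster in grey. ERBB2 splits into 63 lines up to 227 FPKM and 19 lines from 257 FPKM upward, and AR, EGFR and CDKN2A have lower clusters close to 0.

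ESR1, the oestrogen receptor gene, was followed by its known target genes. Its level ran from 0.0002 FPKM to 128 FPKM in HCC1500, with a median of 1.07 FPKM. Over the 82 lines, 333 genes were called, 259 rising with ESR1 and 74 falling. C5AR2 had the highest r, 0.89 (limma, adjusted p = 2.7e-25), and GREB1, PDZK1, SCUBE2 and TFF1, oestrogen-responsive genes, had 0.85, 0.81, 0.77 and 0.72. TFF1 rose by 1.33 ± 0.14 (SE) log2 units per log2 unit of ESR1. CCDC170 at 0.85 and C6orf211 at 0.81, which are neighbours of ESR1 on the chromosome, were also among the top genes. Of the 12 other oestrogen response genes, 11 were called, and the same 11 were called when adjusted over the list alone. STC2 was the exception, with r of 0.22. Of 12 luminal genes 7 were called, also 7 adjusted over the list alone, led by GATA3 at 0.70 and TFF3 at 0.69. ZNF703 in the 8p11 region had 0.71. Genes on the falling side included BTG3 at −0.62, PTPN14 at −0.60 and, among receptors, EGFR at −0.55. ESR1 was close to the rule for a split, with an Ashman's D of 1.72 against the required 2. Without 184A1, 184B5, MCF10A and MCF12A it was split, with 1335 genes called among the upper 40 lines and 3 among the lower 38.

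ERBB2, which encodes the receptor HER2, had 19 lines in its upper cluster, with HCC1419 highest at 4052 FPKM, SUM190 at 2535 FPKM and UACC893 at 2471 FPKM, and 63 lines in its lower cluster, from 4.21 FPKM in DU4475 to 227 FPKM. Among the 63 lower lines 372 genes were called, 250 rising and 122 falling. The counts were 378 and 214 with Spearman's correlation and 300 and 241 without the 2 farthest lines. After upper-quartile scaling, where the lower cluster held 65 lines, they were 159 and 88. PGAP3 at 0.79 (limma, adjusted p = 1.1e-09), ORMDL3 at 0.65 and GRB7 at 0.53 were the 3 called genes of the 12 others in the 17q12 list, also 3 adjusted over the list alone. Luminal genes rose with ERBB2 in 7 of 12 cases, and in 7 adjusted over the list alone, led by ERBB3 at 0.63 and FOXA1 and AGR2 at 0.62 each. Of 17 mesenchymal genes, SNAI2 at −0.59 and CAV1 at −0.53 were called, as they were when adjusted over the list alone. Other falling genes were ACSL4 at −0.65 and ETS2 at −0.62. Among the 19 upper lines only GRB7, with r of 0.84 and a slope of 1.01 ± 0.16 (SE), and MTUS1, with r of 0.83, were called (limma, adjusted p = 0.04 for each). In the 17q12 list 1 gene was called there against 3 adjusted over the list alone, and MED1 and CDK12 in the same region had r of −0.17 and −0.05. Adjusted in the same way, 7 of 15 genes of the 8p11 list were called there, all falling, and 3 luminal genes, all rising. The junction, 8q24 and NRF2 lists had 1 each, and the other lists none. In 1 of 100 permutations 2 or more genes were called over all genes in these 19 lines. The count over all genes was 0 with Spearman's correlation and 0 at a pseudocount of 0.1.

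AR, the androgen receptor gene, was highest in SUM185 at 76.02 FPKM and lay between 0.0001 and 0.0835 FPKM in the 26 lines of its lower cluster. Among the 56 upper lines 227 genes were called. GHR, the growth hormone receptor gene, and NUDT4 had the highest r, 0.67 each (limma, adjusted p = 6.2e-05 for each), although NUDT4 shares its sequence with the pseudogene NUDT4P1. SPDEF at 0.62, FOXA1 at 0.57, GATA3 at 0.56 and XBP1 at 0.50 were the 4 called genes of 12 luminal genes, also 4 adjusted over the list alone. Of 8 other androgen and apocrine genes PIP at 0.54 was called, also 1 adjusted over the list alone. Genes falling with AR included FHL1 and ETS1 at −0.62 each, the basal genes S100A2 at −0.56 and KRT17 at −0.52, and VIM at −0.53. In the lower cluster, whose values are near 0, limma called 0 genes. Of 15951 genes 436 had an unadjusted limma p under 0.05, a share under 0.05, so no excess is seen. The upper count fell to 146 without 184A1, 184B5, MCF10A and MCF12A, where the split also changed, to 57 upper and 21 lower lines.

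EGFR, the epidermal growth factor receptor gene, was highest in MDAMB468 at 1130 FPKM, followed by SUM102 at 210 FPKM. Among the 59 upper lines 435 genes were called, 149 rising and 286 falling. After upper-quartile scaling, with 58 upper lines, 158 rose and 162 fell. ANXA8 at 0.71 (limma, adjusted p = 7.7e-07) and its near-identical copy ANXA8L1 at 0.70 had the highest r, followed by UPP1 at 0.68, CAV2 at 0.66 and the interferon-gamma receptor gene IFNGR1 at 0.66. Basal genes rose with EGFR in 9 of 16 cases, also 9 adjusted over the list alone, led by S100A2 at 0.63 and the laminin genes LAMC2 at 0.61 and LAMB3 at 0.58. IL18, C3, TNFAIP3, BIRC3 and CASP1 had r from 0.60 to 0.62. SLC40A1, the iron exporter gene, had the lowest r, −0.72, and 3 of 13 oestrogen response genes fell, TFF1 and RET at −0.53 each and MYB at −0.51, with 3 called when adjusted over the list alone. In the 23 lower lines limma called 0 genes. Of 15941 genes 602 had an unadjusted limma p under 0.05, a share under 0.05, so no excess is seen. With Spearman's correlation 695 genes were called in the upper cluster.

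CDH1, which encodes E-cadherin, was highest in MDAMB361 at 711 FPKM and lowest in HCC1395 at 0.165 FPKM. Among the 56 upper lines 263 genes were called, against 426 with Spearman's correlation. LRTOMT at 0.69 (limma, adjusted p = 4.9e-05), DEGS2 at 0.67, TMBIM6 at 0.66 and FBP1, a gluconeogenesis gene, at 0.64 had high r, and ESRP2, an epithelial splicing factor gene, had 0.62. Within this cluster luminal genes were called in 7 of 12 cases, also 7 adjusted over the list alone, led by XBP1 at 0.59 and FOXA1 at 0.54. Of 13 other junction genes ESRP2 alone was called, also 1 adjusted over the list alone, and EPCAM had r of 0.09. ACSL4 at −0.65 and SFRP1, a secreted Wnt antagonist gene, at −0.60 fell with CDH1. Among the 26 lower lines 5 genes were called, FAM221A at 0.72 and SELM, OXSR1, COL5A1 and CRTAP from −0.73 to −0.78. That count was 0 with Spearman's correlation and 0 without the expression filter. Of the 5 genes, 0 were among those called after upper-quartile scaling and 0 among those called when 184A1, 184B5, MCF10A and MCF12A were left out, and 1 of 100 permutations of CDH1 over these lines called as many or more.

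VIM had 32 lines in its upper cluster, from 10.7 to 2983 FPKM, and 50 in its lower cluster. Among the upper lines 1148 genes were called, 618 rising and 530 falling. Which direction held more genes depended on the processing and the lines. Counts were 514 rising and 613 falling after upper-quartile scaling, and 450 and 525 without the 2 farthest lines. They were 458 and 591 over 29 upper lines at a pseudocount of 0.1. Without 184A1, 184B5, MCF10A and MCF12A they were 580 and 592 over 30 upper lines. All 14 epithelial junction genes fell as VIM rose, also 14 adjusted over the list alone, with ESRP2 at −0.84 (limma, adjusted p = 4.7e-06), CDH1 at −0.79 and MAL2 at −0.78. ERBB3 fell at −0.82. PRKCDBP at 0.81 and SGCB at 0.80 had the highest r, and the transcription factor genes ZEB1 and ZEB2, which repress epithelial genes, had 0.77 and 0.76. Of the 16 other mesenchymal genes 10 were called, also 10 adjusted over the list alone, including AXL at 0.70 and COL1A1 at 0.62, while FN1, the fibronectin gene, had r of 0.14. Among luminal genes 7 of 12 fell, also 7 adjusted over the list alone, led by ERBB3 and by ELF3 at −0.77. In the lower cluster 73 genes were called, led by VIM-AS1 at 0.64 and ANTXR1 at 0.63. VIM-AS1 is antisense to VIM, and the strand used in counting is not stated, so its value may include reads of VIM. That count fell to 9 without the 2 lines farthest from the median of VIM.

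MKI67, the gene of the proliferation antigen Ki-67, had a median of 22.7 FPKM and a highest value of 71.9 FPKM in HCC1806. Over the 82 lines 420 genes were called, 417 rising and 3 falling, against 297 rising and 9 falling after upper-quartile scaling. The mitotic kinesin genes KIF14 and KIF11 had r of 0.85 and 0.84, ASPM had 0.85, PLK4 0.83 and BUB1B 0.83, the first with a limma adjusted p of 5.9e-20. All 18 other proliferation genes rose, also 18 adjusted over the list alone, from MCM6 at 0.59 to KIF11. Of receptors and oncogenes AURKA at 0.61 and CCNE1 at 0.56 were called, 2 of 30, and 2 adjusted over the list alone. Of tumour suppressors BRCA2 at 0.64 and BRCA1 at 0.52 were called, 2 of 22, and 2 adjusted over the list alone. MYC had r of −0.03 with MKI67. The falling genes were CES2, SNX18P16 and CAPN3, at −0.54 each, but 0 genes fell without the 2 farthest lines, 0 when 184A1, 184B5, MCF10A and MCF12A were left out, and 1 with Spearman's correlation.

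CDKN2A, the gene of the cell-cycle inhibitor p16, was listed at 0 in 6 lines, among them MCF10A, and was at 0.0612 FPKM or less in the 16 lines of its lower cluster. Its highest value was 194 FPKM in BT549. Among the 66 upper lines 523 genes were called, 357 rising and 166 falling, against 305 rising and 268 falling after upper-quartile scaling. NCOA7 at 0.74 (limma, adjusted p = 4e-09), ETS1 at 0.71 and MSN at 0.69 rose with it. Its neighbours MTAP at 0.68 and CDKN2B at 0.63 were called, 2 of the 5 genes tested in the 9p21 list, also 2 adjusted over the list alone. Of 19 interferon-stimulated genes 8 rose, also 8 adjusted over the list alone, led by IFI44 at 0.61, and of 10 HLA class I genes 4 rose, also 4 adjusted over the list alone, led by PSMB9 at 0.65. Luminal genes fell in 7 of 12 cases, also 7 adjusted over the list alone, led by XBP1 at −0.74, FOXA1 and SPDEF at −0.68 each and AGR2 at −0.64. In the lower cluster limma called 0 genes. Of 15943 genes 636 had an unadjusted limma p under 0.05, a share under 0.05, so no excess is seen. Adjusted over the list alone, 6 of 10 HLA class I genes and 1 luminal progenitor gene were called there, and none in the other lists. CDKN2A is close to 0 in these lines and the HLA class I genes move together, so these calls are weak. The split itself rested on few lines. Without SUM229, a line of the lower cluster, CDKN2A was not split and 3 genes were called over 81 lines, which reflects the change of split, since SUM229 is not among the 66 upper lines. When 184A1, 184B5, MCF10A and MCF12A were left out it was also not split and 4 genes were called over 78 lines. That count is over unsplit lines too, so it cannot be set against the 523 of the upper cluster.

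The fourth question was which gene lists moved together or apart, from 784 tests over 406 pairs of lists. Of these, 20 had an adjusted p under 0.05 and 10 also an absolute r of at least 0.5, against 19 called relations after upper-quartile scaling. Luminal and mesenchymal scores were the most opposed, with r of −0.82 over 82 lines (permutation p = 1e-05, adjusted p = 0.00131), rho of −0.75 (permutation p = 1e-05) and r of −0.79 without the 2 lines farthest from the luminal median. The mesenchymal score was close to a split, with an Ashman's D of 1.95. Luminal scores rose with the 11q13 region score, with r of 0.57 over 82 lines (permutation p = 1e-05, adjusted p = 0.00131), rho of 0.62 (permutation p = 1e-05) and r of 0.54 without the 2 farthest lines. Among the 62 lines in the lower cluster of the 17q12 score, that score rose with the luminal score, with r of 0.55 (permutation p = 1e-05, adjusted p = 0.00131), rho of 0.56 and r of 0.51 without the 2 farthest lines, and it fell with the mesenchymal score, with r of −0.56 (permutation p = 1e-05, adjusted p = 0.00131), rho of −0.58 and r of −0.50 without them. Both rho values had a permutation p of 1e-05.

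HLA class I and class II scores rose together, with r of 0.54 over 82 lines (permutation p = 1e-05, adjusted p = 0.00131), rho of 0.51 (permutation p = 1e-05) and r of 0.52 without the 2 farthest lines. Proliferation and housekeeping scores rose together among 74 lines, with r of 0.63 (permutation p = 1e-05, adjusted p = 0.00131), rho of 0.65 (permutation p = 1e-05) and r of 0.62 without the 2 farthest lines. After each line was scaled to the same upper quartile, r over the same 74 lines was 0.47. Epithelial junction scores fell with mesenchymal scores, with r of −0.77 over the 23 lines of the lower junction cluster (permutation p = 3e-05, adjusted p = 0.00336), rho of −0.73 (permutation p = 0.00013) and r of −0.77 without the 2 farthest lines. In the same 23 lines they rose with luminal scores, with r of 0.68 (permutation p = 0.00028, adjusted p = 0.0157), rho of 0.67 (permutation p = 0.00049) and r of 0.63 without the 2 farthest lines. In the 52 lines of the lower androgen and apocrine cluster that score rose with luminal scores, with r of 0.50 (permutation p = 0.00012, adjusted p = 0.00855), rho of 0.45 (permutation p = 0.00083) and r of 0.55 without the 2 farthest lines. It fell with mesenchymal scores, with r of −0.53 (permutation p = 9e-05, adjusted p = 0.00706), rho of −0.46 (permutation p = 0.00065) and r of −0.46 without them. Without the 4 related lines, 3 of these relations lost their call, with r of 0.34 for luminal with androgen scores, 0.64 for luminal with junction scores and −0.46 for androgen with mesenchymal scores. A permutation p of 1e-05 is the smallest that 100000 permutations can give.

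**Figure D4:**
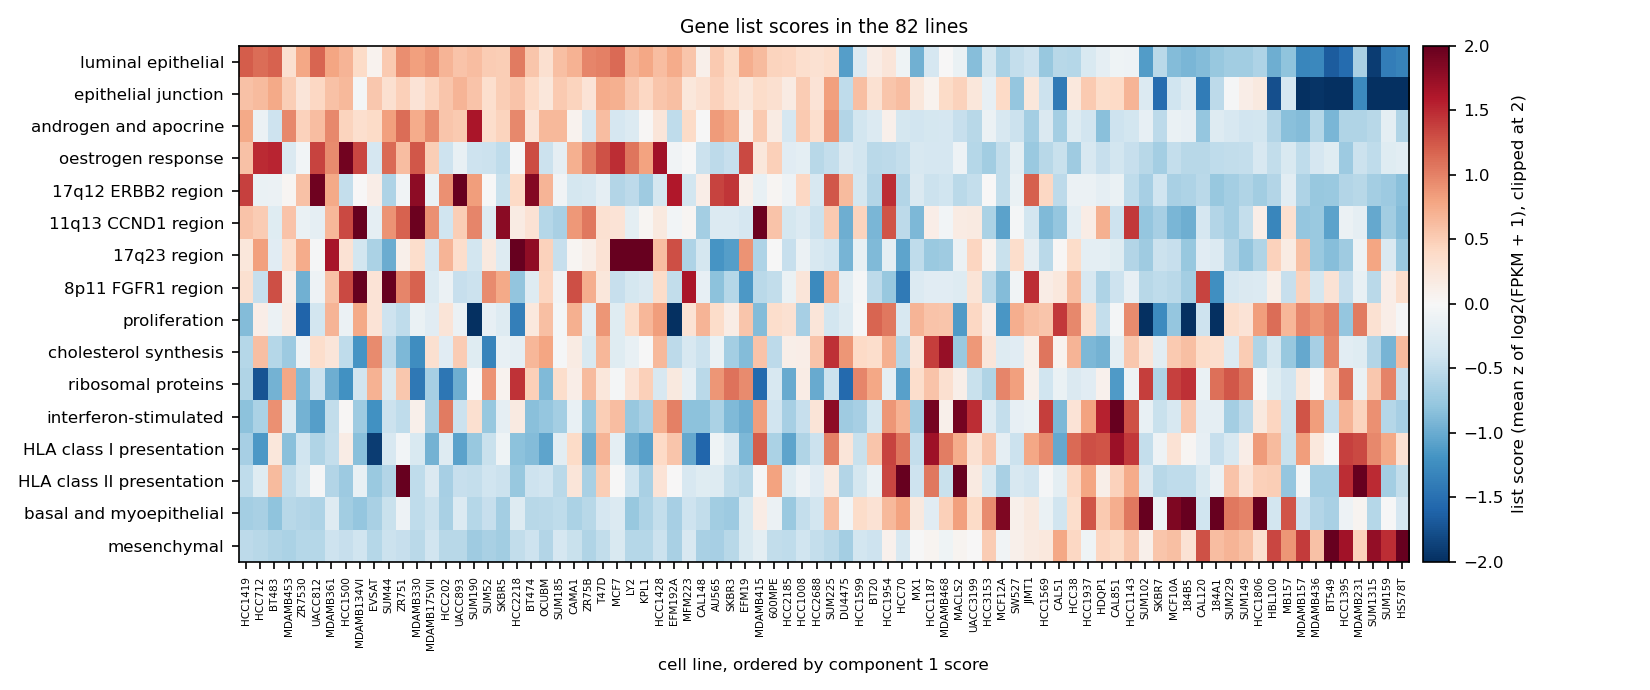
List scores (mean z score of log2(FPKM + 1) over the members, colour, clipped at 2 on either side) of 16 gene lists (rows) in the 82 lines (columns), ordered by component 1 from HCC1419 to HS578T. Luminal and junction scores are high on the left and low on the right, mesenchymal scores the reverse, with r of −0.82 between luminal and mesenchymal scores.

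The last question was which single lines stood far from the others in known receptors, oncogenes and tumour suppressors. Some genes of these lists had a level far above the median in single lines. FGFR2 reached 2766 FPKM in SUM52 and 804 FPKM in MFM223, against a median of 2.91 FPKM. FGFR1 reached 1393 FPKM in MDAMB134VI and 459 FPKM in CAL120, against a median of 17.7 FPKM. FGFR4 was highest in MDAMB453, at 248 FPKM against a median of 5.83 FPKM, and the cyclin D1 gene CCND1 in MDAMB134VI and MDAMB330, at 1278 and 971 FPKM against a median of 91.0 FPKM. By the limit of 3 robust SDs given below, 2 lines lay above the median for FGFR2 and none for FGFR1, FGFR4 or CCND1, whose values spread widely over the lines. AXL was highest in HS578T at 255 FPKM and MDAMB231 at 208 FPKM, and PGR, the progesterone receptor gene, was at 167 FPKM in BT474 and 73.96 FPKM in T47D with a median of 0.0144 FPKM. ERBB3, in contrast, was low in single lines, with 0.204 FPKM in SUM159 against a median of 41.6 FPKM. MYC was highest in SW527 at 280 FPKM and lowest in SKBR5 at 0.605 FPKM.

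Some tumour suppressor genes had very low values in single lines. PTEN had a median of 28.3 FPKM but 0.0231 FPKM in HCC3153, 0.201 FPKM in the line MX1 and 0.241 FPKM in HCC1937. RB1 was at 0.0956 FPKM in DU4475 and 0.483 FPKM in MDAMB468 against a median of 15.3 FPKM, and SMAD4 at 0.0955 FPKM in MDAMB468 against a median of 30.2 FPKM. MAP2K4, a stress kinase gene, was at 0.0124 FPKM in EFM19 and 0.0286 FPKM in DU4475 against a median of 12.003 FPKM. CDH1 was at 0.165 FPKM in HCC1395, 0.182 FPKM in SUM159 and 0.183 FPKM in HCC2185. CBFB was lowest in MDAMB436 at 2.48 FPKM, TBX3 in HCC1187 at 0.0256 FPKM, TP53 in 600MPE at 1.91 FPKM and PIK3R1 in EVSAT at 2.28 FPKM, with PIK3R1 highest in HCC1500 at 226 FPKM. No line lay more than 3 robust SDs below the median for TP53, TBX3 or PIK3R1, and 9 lines did for CDH1. Over 30 receptors and oncogenes 225 values lay more than 3 robust SDs from the gene's median, and over 22 tumour suppressors 51 did. These counts carry no test. Genes that most lines do not express, such as PGR with 22 lines above that limit and none below, gave many of them, and the first count was 132 at a pseudocount of 0.1.

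**Figure D5:**
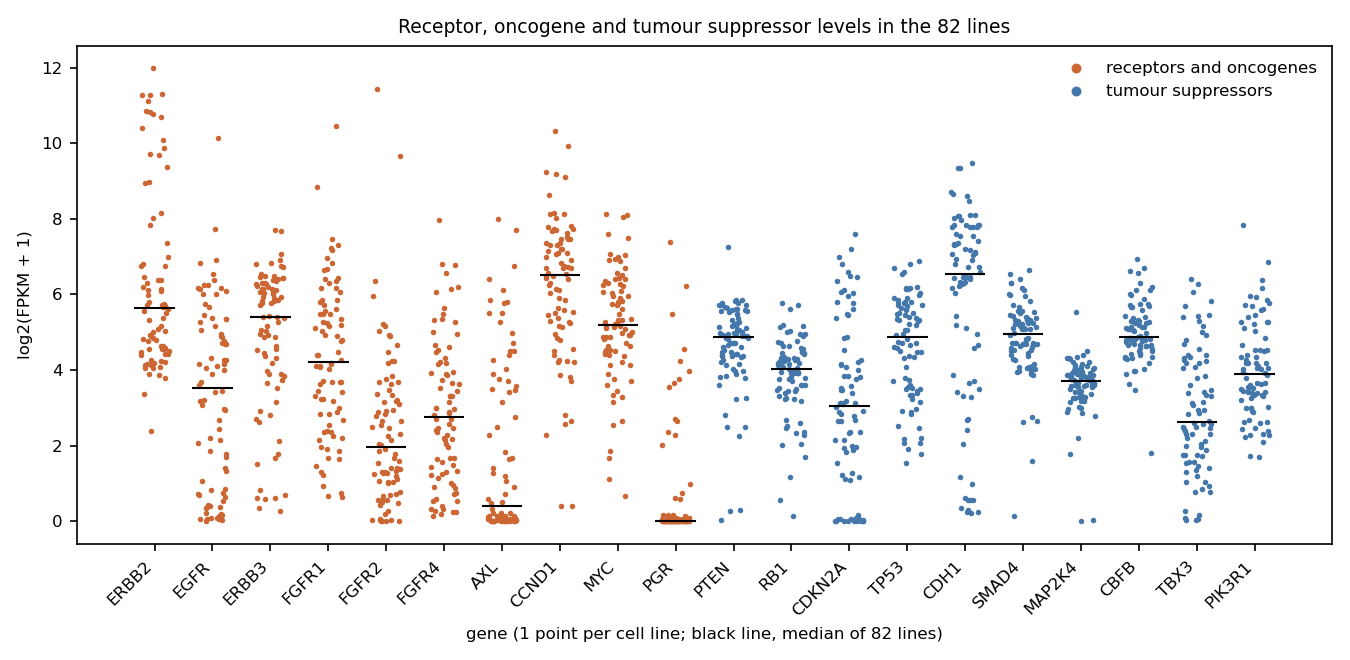
Level as log2(FPKM + 1) (y axis) of the 10 receptor and oncogene genes and the 10 tumour suppressor genes with the largest range (x axis), 1 point per line and a black line at the median of 82 lines. FGFR2 in SUM52 stands at 2766 FPKM above a median of 2.91 FPKM, and PTEN in HCC3153 at 0.0231 FPKM below a median of 28.3 FPKM.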

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

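The replacement of implausible zeros, the omission of SUM229 and the omission of 184A1, 184B5, MCF10A and MCF12A were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because each line has 1 library and no treatment or matched sample. Coherence was called in 26 or 27 lists under every alternative run for it. No called value of a named gene, list or relation changed sign, but the excess of rising over falling genes turned in the upper VIM lines under some alternatives, as given in the report, and in the upper AR lines, from 118 rising and 109 falling to 80 and 115 after upper-quartile scaling, 89 and 112 without the 2 farthest lines, 112 and 129 with Spearman's correlation and 124 and 177 at a pseudocount of 0.1. Of the values of named genes and list relations under the alternatives, 200 SDs were rated the same. Of the mean rho values 306 were rated the same and 1 weaker, and of the r values 2706 the same and 136 weaker. Same does not mean equal here, and for SDs it means within 1.5 times the value. Calls could change even so. Of 333 genes called with ESR1, 195 were also called with Spearman's correlation and 329 without SUM229. Most weaker r values of named genes came with Spearman's correlation (40), without the 2 farthest lines (31) and at a pseudocount of 0.1 (21).

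These counts and shares moved, and the cause was not tested. The list is not complete. Some splits held other numbers of lines, such as 53 lower VIM lines at a pseudocount of 0.1 against 50. Such counts mix the change of processing with a change of lines. At a pseudocount of 0.1, 18 lists were called on component 2 (11 in the report), 0 genes with ERBB2 in the upper cluster (2), 2 with CDH1 in the lower (5), 41 with VIM in the lower (73), and 132 values of receptors and oncogenes lay over 3 robust SDs (225). With Spearman's correlation the scans called 592 genes for the lower ERBB2 lines (372), 0 for the upper (2), 695 for the upper EGFR lines (435), 0 and 426 for the lower and upper CDH1 lines (5 and 263) and 6 for the lower VIM lines (73). With upper-quartile scaling 19 relations were called (10), 247 genes for the lower ERBB2 lines and 3 for the lower CDH1 lines, of which 0 were among the 5 of the report. Without the expression filter 0 genes were called for the upper ERBB2 lines and 0 for the lower CDH1 lines. Without the 2 farthest lines the counts were 1 for the upper ERBB2 lines and 9 for the lower VIM lines, and without the 4 related lines 1 for the upper ERBB2 lines. With genes scaled to unit variance, component 1 held 9.97% of the variance (15.9%) and 7 lists were called on component 3 (13). Without 184A1, 184B5, MCF10A and MCF12A, 6 lists were called on component 3 and 146 genes for the upper AR lines (227). The AR split moved there too, with 57 upper lines (56).

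Some alternatives changed the split of an anchor, so that no matching value exists. A pseudocount of 0.1 split ESR1, with 0 genes among 21 lower and 370 among 61 upper lines, and MKI67, with 184 genes among 76 upper lines. With Ashman's D over 3, AR was not split and 476 genes were called, and CDKN2A was not split and 3 were called. In all, 3 relations weakened without the 4 related lines: luminal with androgen scores (0.34), luminal with junction scores (0.64) and androgen with mesenchymal scores (−0.46). Without 184A1, 184B5, MCF10A and MCF12A the same relations had r of 0.41, 0.66 and −0.49. Depth limits could not be assessed, because the values are FPKM.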

Other observations

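The test of genes 50 steps apart, the component 1 made without the called genes and the permuted component 1 were chosen after results were seen, and the other tests of an explanation in this part before the result that each measures.

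Some pairs of lines were close. Over 3321 pairs the median r was 0.811. SUM149 and SUM229 had r of 0.975, with 4.36% of genes differing 2-fold, AU565 and SKBR3 0.959, KPL1 and LY2 0.952, KPL1 and MCF7 0.943 and LY2 and MCF7 0.940. MB157 and MDAMB157, which catalogues relate, had r of 0.820, rank 1416 of all pairs.

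Genes next to each other on a chromosome rose and fell together over the lines. Adjacent genes had a mean rho of 0.317 over 12628 pairs, against 0.0316 for random pairs, and 4218 of 12444 windows of 10 genes had a mean rho above the highest of 100 shuffled orders, 0.291. The highest window, with a mean rho of 0.716, ran from ZNF808 to ZNF888, which are similar zinc-finger genes whose reads are hard to tell apart, and the next, with 0.702, ran from EXOSC4 to FBXL6. Reads shared between similar genes are argued against as the whole cause, because 11904 adjacent pairs with unlike symbols had a mean rho of 0.303 (SE 0.00825), although 724 pairs with similar symbols had 0.532. Overlap or shared regulation of directly adjacent genes is argued against as the whole cause too, because genes 50 steps apart had a mean rho of 0.147 (SE 0.00599). A candidate explanation is a gain or loss of chromosome arms. At 50 steps, pairs on one side of the largest gap of a chromosome had a higher mean rho than pairs across it, 0.150 against 0.1004, with a mean difference of 0.0494 (SE 0.0157) over 18 chromosomes, higher in 13. Pairs across the gap span it by construction, so they tend to lie farther apart, and mean rho fell with distance, from 0.190 at 20 steps to 0.147 at 50. The difference therefore cannot tell chromosome arms from distance. The arm explanation is a hypothesis, since no copy number was measured and gene order came from another build.

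Proliferation and housekeeping scores rose together, with r of 0.63 (SE 0.0642) over 74 lines. The share of the 10 highest genes is argued against as the whole cause, because the partial r given that share was 0.59 (SE 0.0686). The scaling of the deposited FPKM cannot be told apart from other causes. After upper-quartile scaling r was 0.47 (SE 0.0849), within 1 SE of the threshold of 0.5. Both scores also followed the upper quartile itself, with r of 0.70 and 0.80 before the scaling and 0.61 and 0.52 after it. No biological explanation of this relation was tested.

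Genes correlated with CDKN2A among the 66 upper lines included luminal genes on the falling side, the genes that define component 1. CDKN2A had r of 0.69 with component 1. Given component 1, 3 of the 523 called genes had an absolute partial r of at least 0.5, and 7 did given a component 1 made without the called genes, against at least 325 (median 509) given a permuted component 1. A permuted component is nearly unrelated to CDKN2A, so it was bound to leave most genes and is no control for an axis that follows CDKN2A. The CDKN2A genes may reflect the luminal to mesenchymal axis, but these values cannot tell that axis from CDKN2A itself. Loss of RB1 is known to go with high p16. Given the RB1 mRNA level, 367 of 523 genes kept an absolute partial r of at least 0.5. RB1 was only weakly related to CDKN2A, so it was likely to leave most genes. The count therefore does not decide whether the RB1 level plays a part. Loss of RB1 function that leaves the mRNA was not measured, so RB1 loss itself was not tested. RB1 fell with CDKN2A, with r of −0.34 (permutation p = 0.00521), rho of −0.38 (permutation p = 0.00205), r of −0.40 without the 2 farthest lines and a limma Benjamini-Hochberg adjusted p of 0.0263.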
